A study of Homo sapiens with 14 samples.

How the data were processed

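Loops were measured by HiChIP, with an MNase-based kit per the labels' protocols, in HCT116 cells that carried an empty pSin lentiviral vector or the vector with FOXD2 and were selected with puromycin. The immunoprecipitated marks were H3K4me1, H3K27ac and H3K4me3. The 14 samples form 6 groups by mark and vector, and 8 have loop lists. The other 6 are technical replicates of a replicate 1 sample and have no list of their own in what was used here. By their names, the replicate 1 lists are merged, presumably from the technical replicates the labels give, and the H3K4me1 replicate 2 lists come from a single technical replicate. This difference in processing runs along the replicate number and not along the condition.

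Per the submitters' processing notes, BWA, Juicer and the build hg38 were used, and their versions, settings and the loop caller are not given in the sources used here. Each of the 24 lists (8 libraries at 5, 10 and 25 kb bins) holds 8 columns per line: a pair of anchor bins and the deposited score, a value the authors computed, whose unit is not stated and which is above 2 on every line. The score was used only to describe, rank or filter loops within a list. All loops lie within a chromosome and span at most 2 Mb. The lists give no contact or read counts, so depth is unknown, and the length of a list depends on depth and calling as well as on the cells.

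Loops of different libraries were matched when both anchors started within 1 bin of each other, and matched loops were merged by single linkage, so that a merged loop can cover neighbouring bins. A loop is FOXD2-only for H3K4me1 when it is in both FOXD2 libraries and in neither control, and for the other marks when it is in the FOXD2 list and not in the control list, and control-only is the converse. Genes came from a RefSeq table of the same build with 19974 protein-coding genes placed. That table was used without strand, so either end of a gene inside an anchor bin counted where transcription starts had been planned. For a one-sided loop a gene counts if an end lies in any bin of the merged loop, while loop counts per gene and library use the library's own bins. The median lengths and gene-end shares of one-sided loops use only the first bin pair of each merged loop. Overlaps are Jaccard shares with exact (Clopper-Pearson) 95% intervals for single pairs of libraries. H3K4me1 group values were compared with an exact two-sided permutation test.

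Before the data were examined, the groups, tests, alternatives, 17 gene lists and the rule for named genes were fixed. The rule takes up to 12 genes per direction for H3K4me1 and up to 10 for each other mark, with loops that have no loop of the other condition within 1 bin at 5, 10 or 25 kb, ranked by the number of such loops and then by the best score. It adds list genes with an H3K4me1 one-sided loop, genes with one-sided loops in all 3 marks, FOXD2, MYC and SOX9. Some genes that the rule or the lists name are not reported here. Genes at loops found in all 8 libraries, or in all libraries of a condition, were chosen after their values were seen, as were the examples within lists. The lists cover forkhead, WNT target and feedback, intestinal transcription factor, colon epithelial, foregut and stomach, fetal and regenerative, YAP and AP-1, mesenchymal, TGF-beta and BMP, cell cycle, p53 target, KMT2 and enhancer cofactor, cohesin and loop machinery and HOX genes. Ribosomal protein, histone, and blood and nerve cell marker lists serve for comparison. They hold 512 distinct genes, of which 1 (TROP2, an older name of a gene that is in the same list) was not found in the table. A list's score is the sum over its genes of loops per 1000 listed loops, FOXD2 minus control, set as a percentile among 10000 random lists of the same size matched on loop number.

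The alternatives were the 5 kb and 25 kb lists, lists trimmed to equal length by score, a score limit of 3, matching at 0 or 2 bins, a length filter from 50 kb, gene ends within 5 kb of an anchor, all annotated genes, each H3K4me1 replicate left out and the replicate number as a block. After seeing the data, counting the whole gene span, the comparison of overlaps within and across conditions with its settings and its other pairing of the H3K4me1 libraries, and matching on neighbouring gene ends were added. Loop strength at shared loops was not compared, since the lists give no contact value. Loop matching and list percentiles were tested on simulated data made for the H3K4me1 comparison from 2952 candidate loops. In these, 100% of 200 loops planted each way and of 1500 shared loops were recovered. A planted list of 20 genes reached percentile 100, and 4.5% of 200 unchanged lists fell outside the middle 95 percent. The planted loops lay apart, were in every library of their side and moved by at most 1 bin, within the matching tolerance. Full recovery thus checks the matching itself and not crowded loops or loops missed by a library. In the real H3K4me1 lists, 59.1% of merged loops were in a single library. The planted list was given extra FOXD2 loops, and the unchanged lists were random genes, not neighbours as in some fixed lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.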

Results

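HiChIP, which combines chromatin immunoprecipitation with proximity ligation, was used to list chromatin loops in HCT116 cells, an established human colorectal carcinoma line. The cells stably carried either an empty lentiviral vector (control) or the same vector expressing FOXD2, a forkhead transcription factor, so the design asks which loops differ when FOXD2 is expressed. Loops were captured with antibodies against H3K4me1, a mark of enhancers, H3K27ac, a mark of active enhancers and promoters, and H3K4me3, a mark of active promoters. The 14 samples fell into 6 groups, and loop lists were analysed for 8 of them: 2 control and 2 FOXD2 libraries for H3K4me1, and 1 library per condition for each of H3K27ac and H3K4me3. The H3K27ac and H3K4me3 comparisons therefore have no replicate and carry no test. For H3K4me1, an exact permutation test of 2 against 2 libraries cannot give a p below 0.333. Nothing in the labels says that the replicates came from separate cultures, so these p-values measure only the spread between libraries, which may be technical. Each list gives pairs of anchor bins on the same chromosome (hg38), at most 2 Mb apart, with a score that is the authors' own value. The lists hold no contact counts, so the depth behind a loop is unknown. Values below are from the 10 kb lists unless another bin width is named, and a gene was placed at a loop when either end of the gene lay in an anchor bin.

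STAG1, which encodes a cohesin subunit, had a 10 kb loop that was FOXD2-only in every mark. This 260 kb loop joined the STAG1 end at chromosome 3, 136750001 to 136760000, with the bin at 137010001 to 137020000 that holds an end of IL20RB, a receptor subunit for interleukin-20 family cytokines. It was listed in all 4 FOXD2 libraries, over all 3 marks, with a lowest score of 5.95, and in none of the 4 control libraries. It was not absent from the controls at every bin width, since all 4 control libraries had a 25 kb loop within 1 bin of it. At 25 kb, STAG1 had loops in every library, 7 and 1 in the H3K4me1 controls and 3 and 3 with FOXD2. SOX9, a transcription factor of intestinal stem cells (chromosome 17, 72121020 to 72126416), had 2 and 3 H3K4me1 loops in the FOXD2 libraries against 1 and 0 in the controls, 2 against 0 for H3K27ac and 4 against 3 for H3K4me3. The bin at 72400001 to 72410000 was linked to SOX9 over 280 kb in both FOXD2 H3K4me1 libraries, with scores of 2.64 and 5.40. SOX9 had no FOXD2-only H3K4me1 loop at 5 kb, at 25 kb, with equally long lists or with a score of at least 3, and in the 5 kb H3K4me3 lists it had 2 control loops and 0 FOXD2 loops. TCF7L2, the transcription factor that carries WNT signals with beta-catenin, had 2 and 2 H3K4me1 loops with FOXD2 against 1 and 0, 2 against 1 for H3K27ac and 3 against 2 for H3K4me3. For H3K27ac and H3K4me3 it had control-only as well as FOXD2-only loops. CDK6, a kinase of G1 progression, had 2 and 2 against 0 and 1, 1 against 0, and 4 against 2. At 25 kb the order at CDK6 was the opposite for H3K27ac (2 with FOXD2, 3 in control) and for H3K4me3 (4 and 7).

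**Figure D1:**
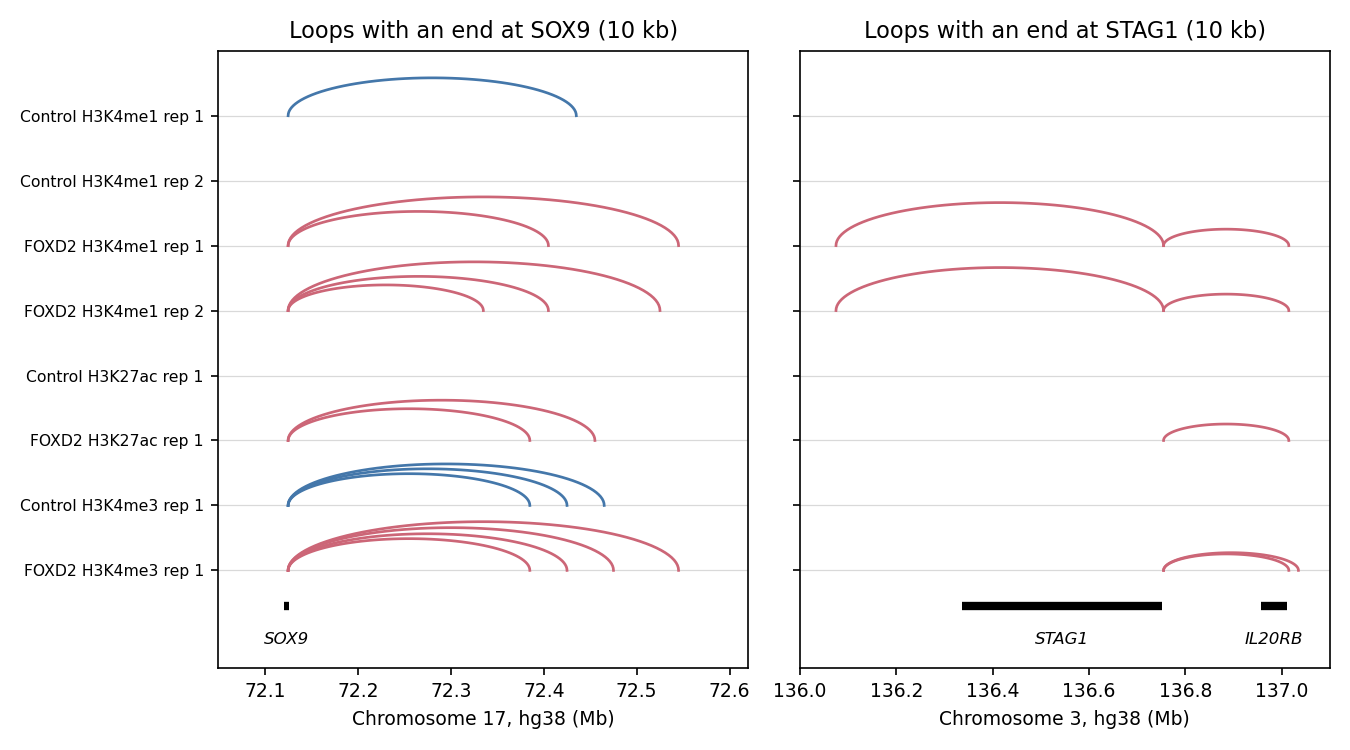
Arcs show each 10 kb loop with an end at SOX9 (left, chromosome 17) or STAG1 (right, chromosome 3) in each of the 8 libraries, by position in Mb on hg38, with control arcs in blue, FOXD2 arcs in red and genes as black bars; arc height follows loop length. STAG1 has arcs in all 4 FOXD2 libraries and no control library, and SOX9 has 2 and 3 in the FOXD2 H3K4me1 libraries against 1 and 0 in the controls.

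Among all H3K4me1 loops, 341 were listed in both FOXD2 libraries and in neither control, and 140 in both controls and in neither FOXD2 library. The FOXD2-only loops lay at 232 protein-coding genes and the control-only loops at 150. Among the genes of the fixed lists, 19 had a FOXD2-only loop. The YAP and AP-1 list gave DUSP5, an ERK phosphatase, F3 (tissue factor), the AP-1 subunit FOSL2 and the YAP paralogue WWTR1. Intestinal transcription factors gave HES1, a Notch target, IRF2BP2, a corepressor, and SOX9. HOX genes gave HOXB7, HOXB8 and HOXC10, and forkhead genes FOXC1 and FOXF1. FOXF1 had 3 and 1 H3K4me1 loops with FOXD2 against 2 and 1, and in the other marks it lay on the control side, with 0 against 5 for H3K27ac and 1 against 5 for H3K4me3. Cell cycle genes gave CDK6 and CDKN2B, an inhibitor of CDK4 and CDK6. The others were EREG, an EGF receptor ligand, the integrin ITGB1, STAG1, TCF7L2 and PECAM1, an adhesion molecule of endothelial cells. IRF2BP2 had 3 and 3 loops with FOXD2 against 0 and 0, F3 had 4 and 3 against 1 and 1, and EREG had 1 and 1 against 0 and 0. ITGB1 had a loop in a single FOXD2 library, with 0 and 1 against 0 and 0. The single FOXD2-only loops at FOXF1, HOXB7 and HOXB8 were lost, and only a control-only loop was left at each, when all lists were made equally long. Under the same setting CDKN2B, F3, HES1, ITGB1, SOX9 and WWTR1 had no FOXD2-only loop, and CDX2 had no control-only loop. The 4 list genes with a control-only loop were CDC25A, a phosphatase that activates cyclin-dependent kinases, CDX2, a homeobox factor of the intestine, the AP-1 subunit JUND, and RNF43, a ubiquitin ligase that removes WNT receptors. JUND had 1 and 2 loops in the controls and 0 and 0 with FOXD2, while CDX2 had 1 and 0 against 0 and 0, and RNF43 had 3 and 2 against 3 and 2. CDC25A had 2 and 1 in the controls and 2 and 2 with FOXD2, and with equally long lists 1 FOXD2-only and 1 control-only loop.

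A stricter set left out loops with a loop of the other condition nearby at any of the 3 bin widths, which left 105 FOXD2-only and 50 control-only H3K4me1 loops. The highest-scoring FOXD2-only genes were PLA2G2F, a secreted phospholipase (best score 8.26), MARK2, a cell polarity kinase (7.53), and SUDS3, a subunit of the Sin3 corepressor complex, which shared its 190 kb loop with the kinase gene TAOK3 (7.12). ZNF609 and OAZ2, an antizyme of polyamine synthesis, shared a 40 kb loop (6.74). They were followed by MATCAP2, MMAA, TRIB1, ST6GALNAC1 with ST6GALNAC2, and PGF, placental growth factor. On the control side stood CRB2, a cell polarity protein (11.9), SRRM3 (6.55), and KAT2A, a histone acetyltransferase, with DHX58 (6.197). They were followed by IQCN, JUND and LSM4 on a shared loop (5.94), KLF10, EBAG9 with SYBU, DYRK3 and NTNG2. CRB2 had 2 and 1 H3K4me1 loops in the controls and 0 and 0 with FOXD2, and DYRK3 and SRRM3 each had 1 and 1 against 0 and 0. With equally long lists, and also with a score of at least 3, no FOXD2-only loop was left at PLA2G2F, MARK2, MATCAP2, MMAA or TRIB1 and no control-only loop at NTNG2. With the score limit none was left at KAT2A, DHX58 or KLF10. MARK2 had 1 and 2 loops in the controls and 1 and 2 with FOXD2, and PLA2G2F 1 and 0 against 1 and 2. Counts were also level at MMAA (1 and 0 against 0 and 1), ST6GALNAC2 (0 and 1 against 1 and 0) and KLF10 (1 and 2 against 2 and 1). EBAG9, SYBU and NTNG2 each had 1 loop in a single control library and 0 and 0 with FOXD2. MATCAP2 (0 and 1) and ST6GALNAC1 (1 and 0) each had 1 loop in a single FOXD2 library and 0 and 0 in the controls. PGF had 1 and 1 loops with FOXD2 against 0 and 0, and at 25 kb 0 and 0 against 1 and 1. The count of FOXD2-only loops was not peculiar to the real split of the 4 libraries: splitting them by replicate number, along which the making of the lists also differed, gave 324 and 141 loops found on a single side, and the remaining split gave 118 and 228. With equally long lists the FOXD2-only and control-only counts were 210 and 152.

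**Figure D2:**
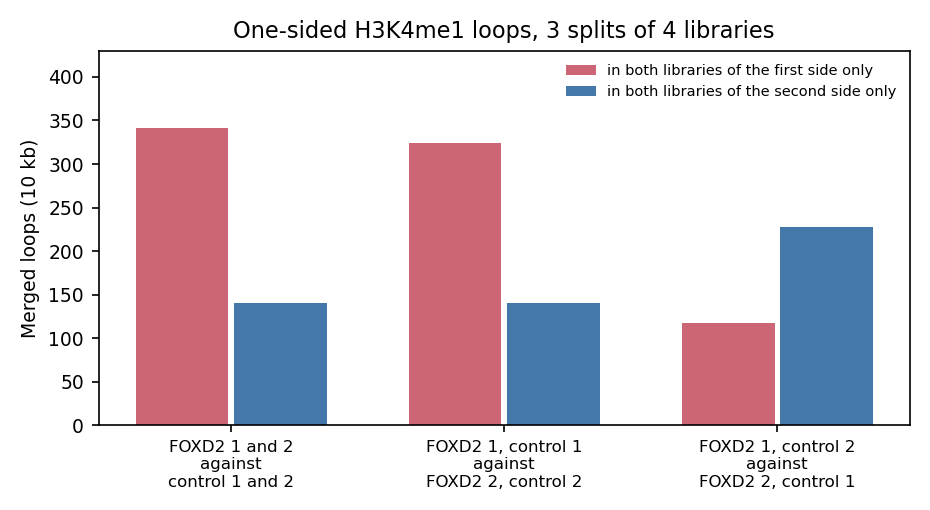
Bars give the number of merged 10 kb H3K4me1 loops listed in both libraries of one side and neither of the other, for the 3 ways of dividing the 4 libraries into pairs. FOXD2 against control gives 341 and 140, replicate 1 against replicate 2 gives 324 and 141, and the remaining division gives 118 and 228.

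For H3K27ac, the FOXD2 library listed 3 loops at YWHAZ, a phosphoprotein-binding adaptor, where the control listed 0, and 3 against 0 at LGR6, an R-spondin receptor. AHNAK2 had 5 against 2, and SNRPE, a spliceosome component, had 4 against 1. TTC24 had 2 against 0, PPP1R1B 4 against 2, and PGF 4 against 0. SERPINB1 had 2 in each library, with 2 FOXD2-only loops. In the control library, CACNA2D2, a calcium channel subunit, CUL9, a cullin, DNPH1, DPEP1, a membrane dipeptidase, and LIMK2, a kinase that phosphorylates cofilin, each had 3 loops against 0 with FOXD2. For H3K4me1, LIMK2 lay on the other side, with 0 and 0 loops in the controls and 1 and 1 with FOXD2. SLC27A4, a fatty acid transporter, had 4 against 1, GFUS 5 against 1, ZZEF1 and CENPX 4 against 2, and LRRC45 5 against 2. Over the whole list, 2766 loops were FOXD2-only, 1954 control-only and 2177 were in both libraries. The ratio of FOXD2-only to control-only loops was 1.42. With 1 list per condition, equally long lists give a ratio near 1 by construction. The direction turned at 25 kb for LGR6, LIMK2 and SERPINB1, and with a stricter score limit for LRRC45. At 25 kb PGF had 0 H3K27ac loops with FOXD2 and 1 in the control.

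For H3K4me3, SIX4, a homeobox factor, and the neighbouring genes ANKRD2 and UBTD1 each had 3 loops with FOXD2 and 0 in the control. VWA7 had 5 against 2, but lay on the control side for H3K4me1, with 1 and 2 loops in the controls and 0 and 0 with FOXD2, and for H3K27ac, with 2 against 0. PSD4 had 3 against 1, EPO, the erythropoietin gene, 3 against 1, and its neighbour POP7 3 against 2. C1orf56 and CDC42SE1 each had 2 against 0. A block of genes on chromosome 17 lay on the control side: ATP5PD, an ATP synthase subunit, had 6 control loops against 0, JPT1 6 against 1, ARMC7 5 against 0, and KCTD2 and NT5C 4 against 1 and 4 against 0. ARMC7, JPT1 and NT5C also had a FOXD2-only H3K4me1 loop, on the other side, with a best score of 2.99. TRAPPC3, a vesicle tethering subunit, C2CD2L and DPAGT1, an enzyme of N-glycan synthesis, each had 4 against 0. HSPA1B, an inducible heat shock protein, had 5 against 2, and CPNE7 4 against 1. In all, 1790 loops were FOXD2-only, 2779 control-only and 2241 were in both libraries. The ratio of FOXD2-only to control-only loops was 0.644. The direction turned at 25 kb for ANKRD2 and UBTD1, and with a stricter score limit for HSPA1B. At 25 kb PSD4 had 0 loops with FOXD2 and 1 in the control, and C1orf56 and CDC42SE1 each had 1 and 2. The order at VWA7 for H3K4me1 and H3K27ac was also the opposite at 25 kb.

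Genes with loops on the same side in all 3 marks numbered 14 for FOXD2, against 9.11 for independent lists. They were ABCC2, a hepatic and intestinal export pump, ANKRD6, CDK6, DNAJC8, DUSP5, F3, IL20RB, NUAK1, a kinase related to AMPK, SCAP, the sterol-sensing escort of SREBP, SOX9, STAG1, SUDS3, TAOK3 and TTF2. NUAK1 had 2 and 1 H3K4me1 loops with FOXD2 against 0 and 0, 1 against 0 for H3K27ac and 2 against 0 for H3K4me3. SCAP had 2 and 1 against 0 and 0, then 2 against 0 and 2 against 0. On the control side, 16 genes stood against 7.03 for independent lists. They were VEGFA, the angiogenic growth factor, KCNK9, a potassium channel, SLC1A5, a glutamine transporter, TICAM1, a Toll-like receptor adaptor, PIEZO1, a mechanically gated channel, CDC25A, BTBD17, CHIT1, FBXO24, IQCN, LOC107985729, MDGA1, MRPL20, NBL1, TMEM278 and VWA1, of which MRPL20, TMEM278, LOC107985729 and VWA1 are neighbours on chromosome 1. Both expected numbers give every gene the same chance, whatever its number of loops. Neighbours on a shared loop, such as SUDS3 and TAOK3, also count as separate genes, so the excess over these numbers was not tested. VEGFA had 2 and 1 H3K4me1 loops in the controls against 0 and 0 with FOXD2, 2 against 0 for H3K27ac and 6 against 3 for H3K4me3. FBXO24 had 1 and 1 against 0 and 0, 2 against 0 and 3 against 0. By listed H3K4me1 loops CDC25A was not lower with FOXD2, with 2 and 1 in the controls and 2 and 2 with FOXD2. At 25 kb, H3K27ac loops at IL20RB, NUAK1, TICAM1 and CHIT1 stood on the opposite side, as did H3K4me1 loops at KCNK9, and with a stricter score the H3K27ac loops at SLC1A5; in the 5 kb H3K4me3 lists MDGA1 had 1 FOXD2 loop and 0 control loops. By the number of loops listed, the order at 25 kb was also the opposite for H3K4me1 at BTBD17, DUSP5, F3, FBXO24, TICAM1 and VEGFA. The same held for H3K27ac at BTBD17, MDGA1 and VEGFA (4 in the control and 5 with FOXD2 at both MDGA1 and VEGFA), for H3K4me3 at CHIT1, IQCN, MDGA1, NBL1 and SCAP, and at 5 kb for H3K4me1 at CHIT1. At 5 kb none of these genes had loops on the same side in all 3 marks, and at 25 kb only STAG1 and SUDS3 did. At 5 kb, at 25 kb, with equally long lists and with a score of at least 3, there was no FOXD2-only H3K4me1 loop at ANKRD6, F3, SCAP or SOX9. In the same 4 settings there was no control-only H3K4me1 loop at BTBD17, FBXO24, LOC107985729, MRPL20, SLC1A5, TICAM1, TMEM278, VEGFA or VWA1.

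Over genes with loops on a single side in a pair of marks, 109 had H3K4me1 and H3K27ac loops on the same side and 50 on opposite sides, an odds ratio of 4.23. For H3K4me1 with H3K4me3 the counts were 99 and 71 (2.48), and for H3K27ac with H3K4me3 561 and 416 (2.13). The ratios also depend on how the H3K4me1 libraries are divided. By replicate number they were 0.831 with H3K27ac and 1.89 with H3K4me3, and in the remaining division 1.31 and 0.232. In divisions not made by condition it is arbitrary which side comes first, so a ratio and its inverse mean the same. The inverse of 0.232 exceeds every ratio found by condition, so an association this strong arose in a division not made by condition.

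FOXD2 itself (chromosome 1, 47438044 to 47440691) had few loops in either condition. For H3K4me1 it had 0 and 1 in the controls and 0 and 0 with FOXD2, for H3K27ac 1 in the control and 0 with FOXD2, and for H3K4me3 1 in each. MYC, a WNT target and driver of proliferation (chromosome 8, 127735434 to 127742951), had 3 and 2 H3K4me1 loops in the controls and 2 and 4 with FOXD2. Its H3K27ac loops numbered 1 in the control and 0 with FOXD2, and its H3K4me3 loops 1 and 4. At 25 kb the H3K27ac loops at MYC numbered 5 in the control and 8 with FOXD2 and the H3K4me3 loops 11 and 11, and at 5 kb its H3K4me3 loops numbered 2 and 0.

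Colon epithelial genes had more H3K27ac loops with FOXD2: the markers KRT8 and KRT18 (keratins), GPA33, MUC12 and ESRP2, a splicing regulator of epithelial cells, had FOXD2-only loops and no list member had a control-only loop. Summed over its genes, loops at the list numbered 3.22 per 1000 listed loops with FOXD2 and 1.20 in the control, at the 99.9 percentile of 10000 random lists. In such sums a loop shared by several members counts for each. The random lists drew genes one by one, so percentiles of lists with neighbouring members can be too extreme. Mesenchymal genes were on the same side, with FOXD2-only H3K27ac loops at members that included ACTA2, ITGA2, SNAI2, TGFB1, TGFBI and TGFBR2 and a control-only loop at SPARC (2.82 against 1.20 per 1000, percentile 99.2). For H3K4me3, WNT target and feedback genes stood at 7.91 with FOXD2 and 5.16 in the control (percentile 99.7), with 9 members that had a FOXD2-only loop, among them MYC, SOX9, TCF7L2 and ZNRF3, and 6 that had a control-only loop. RNF43 and TCF7L2 were in both counts. YAP and AP-1 genes stood at 7.17 and 4.56 (percentile 99.7), histone genes at 3.46 and 0.793 (percentile 99.985), where 8 genes shared 6 merged FOXD2-only loops on 2 chromosomes. Ribosomal protein genes lay the other way, at 3.71 with FOXD2 and 7.54 in the control (percentile 0.36): 18 had a control-only H3K4me3 loop, such as RPL19 and RPS18, and 2 had a FOXD2-only loop, RPL4 and RPL8, RPL8 being in both counts. These 6 of 51 pairs of list and mark fell outside the middle 95 percent, and they depended on the bin width and, for 3 of them, on other settings. Some lists fall outside that range without any change, as did 4.5% of unchanged lists in the simulated H3K4me1 data. At 25 kb all 6 pairs lay inside it, and the pairs outside it were others. In the 5 kb and 25 kb lists the percentiles were 10.1 and 63.7 for colon epithelial markers, 33.6 and 89.4 for mesenchymal genes, 61.6 and 54.9 for WNT genes, 17.3 and 95.4 for YAP and AP-1 genes, 65.4 and 39.3 for ribosomal protein genes, and 99.6 and 21.1 for histone genes. With a score of at least 3, colon epithelial markers stood at 90.9, mesenchymal genes at 83.1 and YAP and AP-1 genes at 91.9. Mesenchymal genes stood at 91.0 with gene ends within 5 kb of an anchor and at 91.9 with the whole gene span, and YAP and AP-1 genes at 96.7 with equally long lists.

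None of the 17 lists left the middle 95 percent for H3K4me1. The highest were YAP and AP-1 genes (96.4), intestinal transcription factors (96.1) and cohesin and loop machinery genes (94.6). The cohesin list also stood at 96.7 for H3K27ac, with NIPBL, STAG1 and WAPL FOXD2-only, and at 96.8 for H3K4me3. In the order H3K4me1, H3K27ac and H3K4me3, the percentiles were 73.8, 4.51 and 42.0 for forkhead genes, 5.56, 33.0 and 83.1 for foregut and stomach genes, and 90.3, 23.1 and 86.0 for fetal and regenerative intestinal genes. They were 22.7, 83.1 and 97.3 for TGF-beta and BMP genes, 83.6, 80.5 and 85.8 for cell cycle genes, and 28.8, 86.3 and 77.7 for p53 targets. For KMT2 and enhancer cofactor genes they were 89.7, 28.7 and 68.6, for HOX genes 29.7, 90.3 and 86.1, and for blood and nerve cell markers 56.8, 30.9 and 17.6. The other pairs were H3K4me1 with WNT (68.6), colon epithelial (41.3), mesenchymal (57.6), ribosomal protein (18.6) and histone genes (84.9). For H3K27ac they were WNT (29.3), intestinal transcription factors (89.8), YAP and AP-1 (60.2), ribosomal protein (41.5) and histone genes (54.1), and for H3K4me3 intestinal transcription factors (50.6), colon epithelial (55.9) and mesenchymal genes (59.9).

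**Figure D3:**
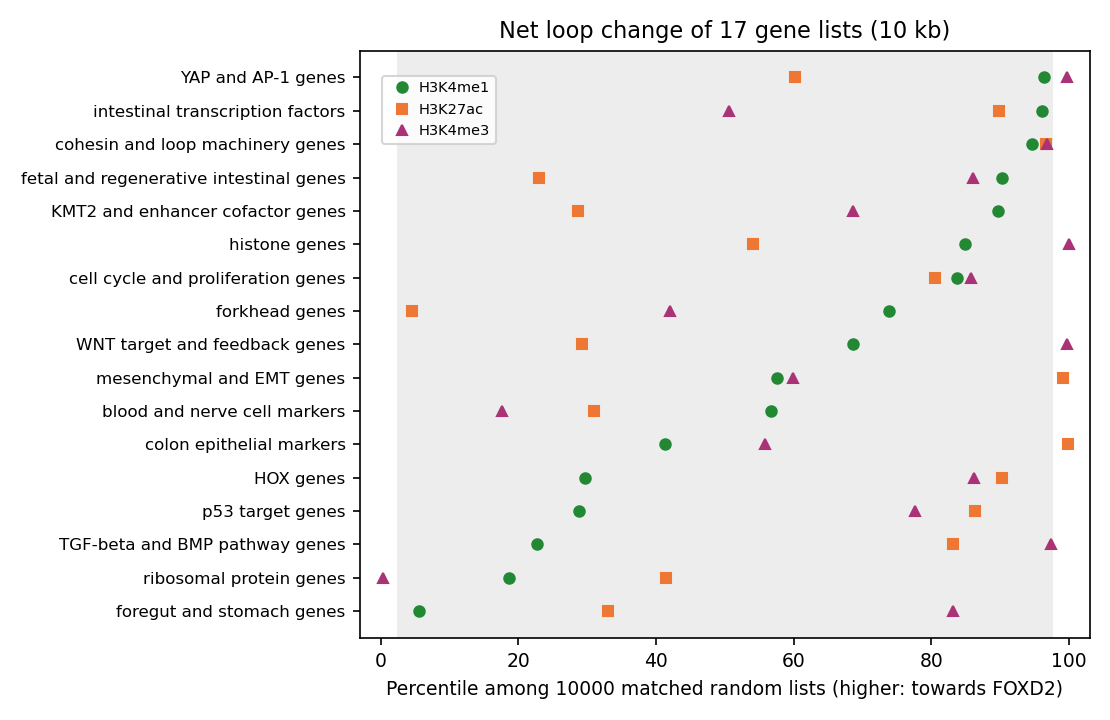
Each point is the percentile, on the horizontal axis, of a gene list's net loop change (FOXD2 minus control, per 1000 listed loops) among 10000 random lists matched on loop number, for the 17 lists and the 3 marks at 10 kb; the grey band is the middle 95 percent. Points outside the band are 2 lists for H3K27ac and 4 for H3K4me3, of which ribosomal protein genes (0.36) lie on the control side.

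Loops were listed in different numbers. The H3K4me1 libraries held 3483 and 2459 loops in control cells (2971 ± 724, SD, n = 2) and 3606 and 3479 with FOXD2 (3542.5 ± 89.8, SD, n = 2), a ratio of 1.19 that did not exceed the spread between libraries (exact permutation p = 0.667). Within replicate 1 the ratio was 1.04 and within replicate 2 it was 1.41. At 5 kb the ratio was 1.36 (exact permutation p = 0.333, the lowest the design allows), and 1.22 and 1.53 within the replicates. At 25 kb it was 1.12 (exact permutation p = 1). H3K27ac loops numbered 4156 in the control and 4962 with FOXD2, a ratio of 1.19. H3K4me3 loops numbered 5043 and 4047, a ratio of 0.802, which was 0.995 in the 25 kb lists (10298 and 10244 loops).

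Loops with gene ends at both anchors made up 26.3% of H3K4me3 loops in the control (95% exact interval 25.1 to 27.6) and 22.3% with FOXD2 (21.01 to 23.6), and 13.5% and 11.5% of H3K27ac loops. Such intervals cover counting error only. For H3K4me1 the shares were 8.35% and 13.4% in the controls and 8.85% and 8.62% with FOXD2 (difference -2.13 points, exact permutation p = 1), and without control replicate 2 the difference was 0.380 points. The gene-dense chromosomes 11, 16, 17 and 19 carried 29.1% of H3K27ac loops in the control and 25.8% with FOXD2, 29.2% and 25.9% of H3K4me3 loops, and 20.7%, 26.8%, 21.6% and 20.6% of loops in the H3K4me1 libraries (controls 1 and 2, then FOXD2 1 and 2). The median loop length was 120 and 90 kb in the H3K4me1 controls and 120 and 100 kb with FOXD2 (exact permutation p = 1), 90 and 110 kb for H3K27ac, and 100 and 110 kb for H3K4me3. By the first bin pair of each merged loop, FOXD2-only H3K4me1 loops had a median of 130 kb and 43.1% had a gene end (37.8 to 48.6). Control-only loops had a median of 90 kb and 55.0% had a gene end (46.4 to 63.4). In every division of the 4 libraries, the side with control replicate 2 had the shorter median and the higher share with a gene end. By replicate number the shares were 49.6% with it and 39.2% without it, and in the remaining division 59.3% and 38.6%. The difference in gene ends was thus not told from this library's own character.

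**Figure D4:**
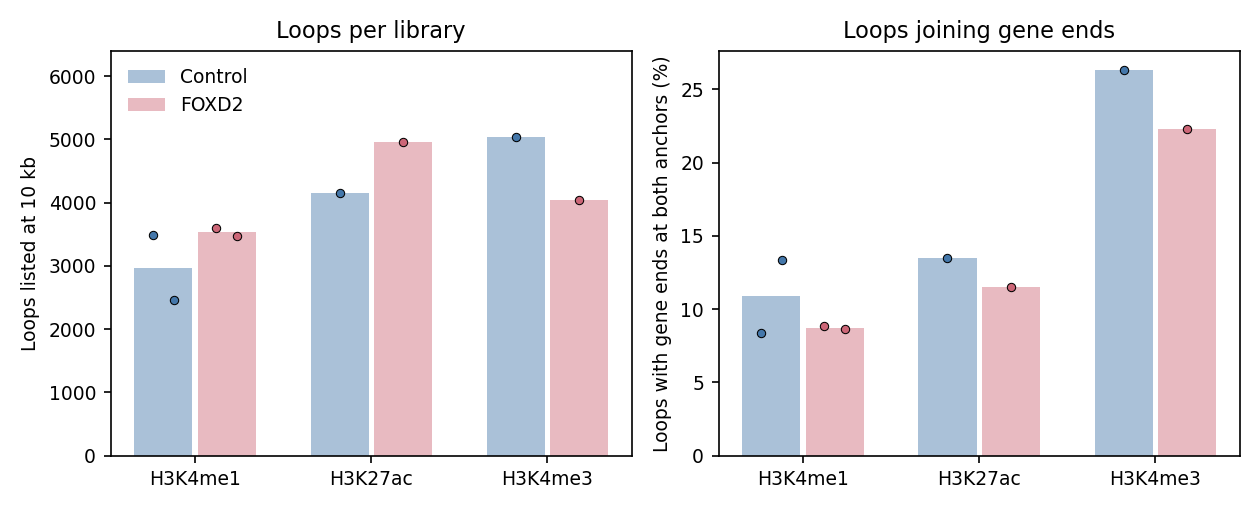
Bars give group means and points single libraries, for the number of loops at 10 kb (left) and the percent of loops with gene ends at both anchors (right), by mark and condition. Control replicate 2 of H3K4me1, with 2459 loops and 13.4%, stands apart from the other 3 H3K4me1 libraries (3479 to 3606 loops and 8.35% to 8.85%).

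Loops at GPRC5C, SP2 and NR6A1, which encode a G protein-coupled receptor, a zinc finger factor and a nuclear receptor, were listed in every library. Of 13401 merged loops over the 8 libraries, 530 were in all 8 (3.95%) and 7576 in a single library (56.5%). A loop listed in all 8 joined 74370001 to 74380000 with 74450001 to 74460000 on chromosome 17, at GPR142 and GPRC5C, with a score of at least 35.4 in each list. Others lay at SCRN2, SP2 and SP6 (at least 27.9) and at NR6A1, OLFML2A, RPL35 and WDR38 (at least 25.0).

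The overlap of loops was compared within and across conditions over all marks, a comparison added after the data were seen. The 8 libraries were set in 4 pairs of a control and a FOXD2 library, with H3K4me1 paired by replicate number, and the share of loops in common was taken between every 2 pairs. Averaged over both conditions, libraries of the same condition shared 1.49 points more of their loops than libraries of different conditions, and the difference was above 0 in 6 of 6 combinations (0.821 to 2.68 points). It is not settled whether the replicate number links the H3K4me1 libraries. With the H3K4me1 pairs crossed the value was 1.29 points, again above 0 in 6 of 6 combinations (0.354 to 2.49 points). The lowest was the combination within H3K4me1, which was -0.182 at 5 kb and -1.53 at 25 kb with crossed pairs. For FOXD2 H3K27ac and FOXD2 H3K4me1 replicate 1 the share was 32.0%, and it was 25.6% for the corresponding controls, against 28.7% and 26.5% across conditions. The excess lay with the FOXD2 libraries: they shared 28.0% on average, against 24.5% across conditions, and were above the mean across conditions in 6 of 6 combinations. Control libraries shared no more with each other (24.0%) than with FOXD2 libraries, and were above that mean in 2 of 6. The highest value among the other 7 assignments of condition was 0.33 (0.474 with crossed pairs), and 8 assignments are too few for a share under 0.05. Within H3K4me1 alone, the 2 pairs of the same condition shared 28.7% and 32.7% and the 4 pairs across conditions 27.5% to 33.2%, so the means of 30.7% and 29.7% differed by 0.942 points, less than the range across pairs, and by -2.10 points without FOXD2 replicate 2. The control and FOXD2 lists shared 31.6% of loops for H3K27ac (30.5 to 32.7) and 32.9% for H3K4me3 (31.8 to 34.0), against at most 1.14% after shifting a list by 1 Mb.

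**Figure D5:**
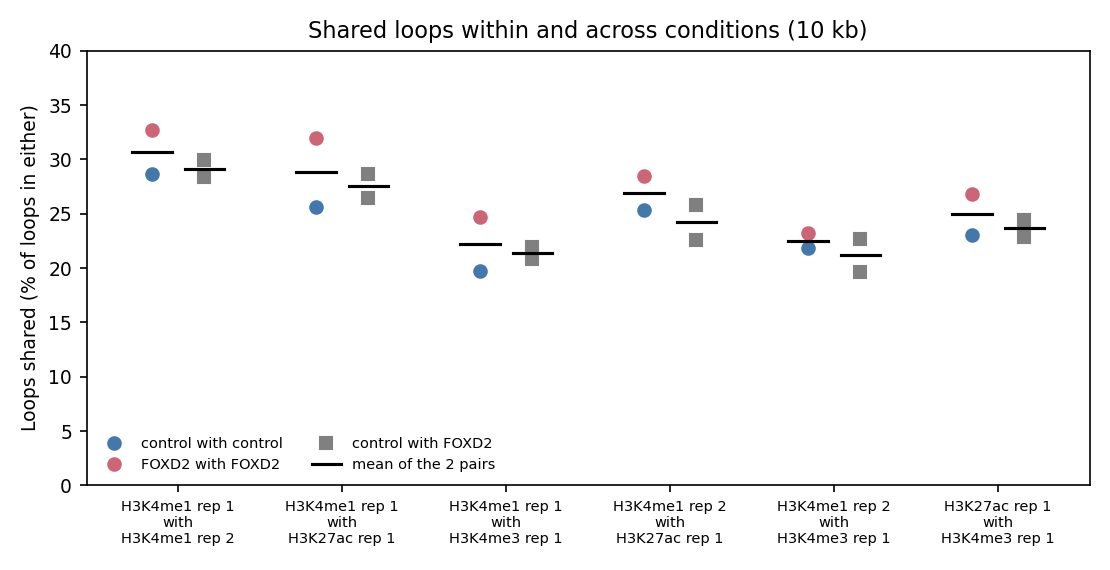
Points give the percent of 10 kb loops shared by 2 libraries for the 6 combinations of library pairs, with control with control in blue, FOXD2 with FOXD2 in red, control with FOXD2 as grey squares and the mean of each 2 as a line. The within-condition mean lies above the across-condition mean in 6 of 6 combinations, by 0.821 to 2.68 points, with H3K4me1 libraries paired by replicate number.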

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

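Comparison with the 5 kb and 25 kb lists was fixed before the data were examined, but of the tests in this part, their use to weigh a bin-width property was chosen only after the result was seen, and matching on neighbouring gene ends was added after the data were seen. The number of listed loops moved in opposite directions in different marks: FOXD2 over control was 1.19 for H3K27ac (4156 to 4962 loops) and 0.802 for H3K4me3 (5043 to 4047). The difference between the marks was not tested, since each condition had 1 library per mark, and at 25 kb the H3K4me3 ratio was 0.995.

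Ribosomal protein genes, a list meant for comparison, had the lowest H3K4me3 percentile of the 17 lists, with 18 genes on the control side and 2 on the FOXD2 side. The longer control list is argued against as the whole cause, since with equally long lists 14 genes still had a control-only loop and 3 a FOXD2-only loop. A general loss of loops in gene-dense regions is also argued against as the whole cause, since the percentile was 0.81 among random lists with as many neighbouring gene ends. It may account for a part: the mean score of random lists was -0.480 without this matching and -0.942 with it. The score of the ribosomal protein list was -3.83. The pattern was seen at 10 kb only, with percentiles of 64.8 at 5 kb and 38.9 at 25 kb in a separate draw of random lists, so a property of that bin width is a candidate explanation. A change at these genes with FOXD2 stays open as an untested alternative, and a second H3K4me3 library per condition would test it.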

How the results depend on the processing

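Of the values here, those for the whole gene span and for overlaps within and across conditions over all marks come from tests chosen only after the data were seen. Over 167 results on named genes, 864 of 1169 alternatives kept the loops on the same side, 283 left none or added some, and 22 turned. Gene ends within 5 kb, all annotated genes and the whole gene span could only add genes to the same loops. These settings kept the side by construction, so the count of 864 overstates how stable the named genes were. All losses and turns came from the 5 kb and 25 kb lists, equal lists and the stricter score. For the 6 list percentiles 25 of 42 kept their side and range, 12 moved inside the middle 95 percent and 5 turned. For 21 other results 93 of 161 counted as unchanged, 63 as moved and 5 turned. Unchanged meant within the spread or 1.5 times the count for most of these results. For the H3K4me1 loop ratio, median length and gene ends at both anchors it meant only that the direction did not reverse, whatever the size. For overlap within minus across conditions it meant only a value above 0. Overlap within minus across conditions, 1.49 points, ranged from 0.749 to 1.95, and from 0.472 to 1.53 with the H3K4me1 pairs crossed, and stayed above every other assignment. Unless a construction is named, the cause was not tested. The unknown depth limits every count.

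Loops listed, FOXD2 over control, were for H3K27ac 1.08 at 5 kb and 1.29 with a stricter score, and for H3K4me3 0.691 at 5 kb and 0.995 at 25 kb. For H3K4me1 leaving out a replicate gave 1.02 (without control 2) to 1.44. The FOXD2 minus control median length became 30 kb with equal lists and 10 kb with the length filter for H3K27ac, 0 kb at 25 kb and with the length filter for H3K4me3, and -10 to 20 kb on leaving out an H3K4me1 replicate (-10 without control 2, -5 without FOXD2 1). Gene ends at both anchors differed by 0.108 points for H3K4me1 with the whole gene span and by -4.64 to 0.380 on leaving out a replicate, and for H3K4me3 by -0.832 at 5 kb and -2.15 with the whole gene span.

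Shared loops in percent, in the order 5 kb, 25 kb, equal lists, stricter score, 0 bins and 2 bins, were 18.6, 37.3, 32.3, 32.8, 18.3 and 33.1 for H3K4me1 and 20.3, 39.0, 32.8, 36.3, 17.3 and 36.3 for H3K27ac. For H3K4me3, where equal lists stayed within the interval, the others were 22.5, 42.6, 34.9, 19.2 and 38.1. Leaving out a replicate gave 27.9 to 31.6 for H3K4me1, and -2.10 to 4.796 points for within minus between. FOXD2-only H3K4me1 loops numbered 102 at 5 kb, 756 at 25 kb, 210 with equal lists, 217 with a stricter score and 481 to 1579 on leaving out a replicate, and control-only loops 30, 377 and 247 to 1350, since fewer libraries ask less of a loop. FOXD2-only over control-only was 1.13, 1.56, 1.00, 1.76, 1.29 and 1.52 for H3K27ac in the order above, and for H3K4me3 0.552, 0.988, 1.00 with equal lists and 0.722 with 0 bins; equal lists give a ratio near 1 by construction.

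List percentiles that turned were colon epithelial 10.1, mesenchymal 33.6, YAP and AP-1 17.3 and ribosomal protein 65.4 at 5 kb, and histone 21.1 at 25 kb. At 5 kb 1 pair of list and mark lay outside the middle range. At 25 kb all 6 pairs that were outside it at 10 kb lay inside, and the pairs outside were others. Genes FOXD2-only in all 3 marks numbered 3 at 5 kb (none of the 14 at 10 kb), 101 at 25 kb (2 of the 14), 27 with ends within 5 kb, 34 over all genes and 37 with the whole span. Control-only genes numbered 2 at 5 kb and 25 at 25 kb (none of the 16 at 10 kb), 9 with equal lists, 7 with a stricter score, 10 at 2 bins and 28 with ends within 5 kb. Values of -1, that is, no loop on the named side and 1 on the other, were found at FOXF1 (equal lists, stricter score), HOXB7 and HOXB8 (equal lists), KCNK9 and PGF (25 kb) for H3K4me1; at CDK6, CHIT1, IL20RB, LGR6, LIMK2, NUAK1, SERPINB1 and TICAM1 (25 kb), LRRC45 and SLC1A5 (stricter score) for H3K27ac; and at ANKRD2 and UBTD1 (25 kb), HSPA1B (stricter score) and MDGA1 (5 kb) for H3K4me3. They were -2 for H3K4me3 at CDK6 (25 kb) and SOX9 (5 kb).

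With the replicate number as a block, the H3K4me1 loop ratio was 1.21 and the shared percent 30.3. Directions differed within the replicate numbers: gene ends at both anchors differed by 0.492 points in replicate 1 and by -4.76 in replicate 2, and the 25 kb loop ratio was 0.97 and 1.38. Whether the numbers pair the libraries is not settled. Deviations of same-numbered libraries correlated at 0.0311 over 7302 merged 10 kb loops, most of them in a single library. At 25 kb, same-numbered control and FOXD2 H3K4me1 libraries shared 41.5% and 36.2%, against 37.0% and 34.6% with the numbers crossed. Dividing by number gave 1285 and 216 one-sided loops there, against 756 and 377 by condition. Not run were loop strength, which needs contact values, and 5' ends of all transcripts, which need strand. Equal lists give no value for the loop ratio.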

Other observations

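The comparison of overlaps and all its tests were added after the data were seen. Of the tests in this part, those of equal list lengths, of swapped conditions, of crossed pairs and of loop length were chosen only after the result was seen, and the count of loops in every library of a condition was also added then. In all 4 FOXD2 libraries and no control, 18 loops were listed, against 3 in all 4 controls and no FOXD2 library. Other assignments, made by swapping conditions within pairs that followed the replicate number for H3K4me1, gave at most 11. A division of the H3K4me1 libraries by replicate number was not among these assignments. Next to the STAG1 and IL20RB loop the 18 loops include a 710 kb loop at NUAK1, a 220 kb loop at TTF2, and loops at IFIT1B, an interferon-induced family member, SPINT1, an inhibitor of serine proteases, CABP1 with MLEC, GOT1, a transaminase, SCAP, and DNAJC8 with EYA3. The other 9 had no gene end, among them a 290 kb loop on chromosome 16 from 81400001 to 81690001. The same anchor at 81400001 had a 180 kb loop to 81580001 in all 4 controls and no FOXD2 library. The other control loops were a 110 kb loop at KCNK9, with a lowest score of 18.2, and a 40 kb loop at GGCX and MAT2A. Most of these loops had a 25 kb loop of the other condition within 1 bin: only 3 of the 18 (at SCAP, at SPINT1 and without a gene end) and 1 of the 3 (at GGCX and MAT2A) had none at any bin width, and all 4 controls had one near the loops at STAG1 and IL20RB and at NUAK1. At 5 kb the FOXD2 count was 2, under the highest other assignment (5), and with a stricter score it was 9, equal to the highest other.

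Averaged over both conditions, libraries of the same condition shared 1.49 points more loops than libraries of different conditions. Only FOXD2 libraries shared more (28.0%, against 24.5% across conditions), while control libraries shared 24.0%. For the average, the real assignment was the 1 of 8 with the highest value (highest other 0.33), too few assignments for a share under 0.05. The pairs followed the replicate number for H3K4me1. With these pairs crossed the value was 1.29 (highest other 0.474). Unequal list lengths are argued against for the average, since equal lengths gave 1.82 (highest other 0.140), and 1.48 with crossed pairs (highest other 0.515). A copy-number difference of a single chromosome is argued against, since leaving out each in turn gave at least 1.41, and 1.21 with crossed pairs. Differences in loop length and gene density are argued against only at a coarse level. The 6 strata were loops up to or over 100 kb with and without a gene end, and gene-dense and other chromosomes. The lowest value in a stratum was 0.689, and 0.530 with crossed pairs, and the real assignment was highest in each under both pairings. With crossed pairs, the combination within H3K4me1 was below 0 in both strata without a gene end (-0.190 and -0.477). Finer differences within a stratum were not tested. A higher overlap of the FOXD2 lists from their quality or depth was not tested and stays open. A biological difference with FOXD2 stays open as a hypothesis, as does any difference between the control and FOXD2 cells or their preparation that all marks share, and a separately made pair of lines would test it.

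More H3K4me1 loops were FOXD2-only than control-only, and they were longer. The shorter list of control replicate 2 stays open as a source of the excess, since with equal lengths the ratio was 1.38 (1.12 to 1.71), an interval that includes the highest ratio of the other divisions, 1.20. For the length, the shorter loops of control replicate 2 are a candidate explanation, since in all 3 divisions the side without it had a median of at least 130 kb and the side with it at most 110 kb. An effect of FOXD2 on either was not told from this library's own character, and another control library would test it.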
